A study of Mus musculus with 28 samples.

How the data were processed

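Total RNA from the whole brain of 28 mice was hybridised to Affymetrix U74Av2 arrays, 1 per mouse, per the labels. The deposited values are signal intensity per probe set on a linear scale, made by the authors with MAS5, per the submitters' processing notes; its version is not given in the sources used here. On every array the mean signal with the lowest and highest 2% left out was 150, so the arrays had been scaled to a common level, and the values were used as deposited. Signals ranged from 0.0251 to 19046.3 and array medians from 43.6 to 61.1. No detection call or background value was used here, so a weak signal cannot be set against background, and the number of arrays limits the precision. No pair of arrays was identical, and rank correlations within groups ran from 0.907 to 0.972. The labels give each sample as 1 mouse, so replicates are animals.

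Of 12488 probe sets, 66 controls were left out. By the platform annotation 10833 had 1 gene, 396 several and 1193 were not listed; genes were named from those with 1. Gene symbols were checked through gene identifiers against a mouse gene table (GRCm38.p6), which was used for names and gene order only, and 10817 matched. A probe set was kept when its signal exceeded the median of its own array in at least 3 arrays, which left 7350 (59.2%) and 5599 genes. Values were taken as log2.

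Differences were tested with limma (version 3.58.1, R 4.3.3; lmFit and eBayes with a variance trend) with 1 mean for each of 6 groups and all 28 arrays in the fit, so that groups share an estimate of spread. P-values were adjusted by Benjamini-Hochberg over the probe sets kept, two-sided, at 0.05. Contrasts were seizure against untreated averaged over genotypes with equal weights and in each genotype, each mutant against wild-type before and after seizure, and the interaction as an F test. Errors of log2 changes are SE. Of 33 gene lists, 32 had at least 3 measured genes and were tested with camera (preset correlation 0.01, estimated correlation as an alternative) on 1 probe set per gene, the one with the highest mean signal, adjusted over the lists within a contrast. The lists cover early transcription factors, activity-regulated effectors, MAP kinase feedback, glucocorticoid, circadian, cytokine, stress, metabolic, receptor, channel, neuropeptide and synaptic genes, ribosomal proteins, transcription factor families, and markers of cell types and brain regions. Fisher exact tests and permutation tests (exact, or 100000 resamples) were used for shares and array quality.

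The genes named were fixed by rule before the data were examined: up to 12 risen and 12 fallen genes with the smallest adjusted p in each contrast, up to 4 members with the smallest p in each list described, the receptor genes Chrnb4, Chrna7, Chrna3 and Chrna5 throughout, Fos, Fosb, Junb, Egr1, Nr4a1 and Arc in seizure contrasts, and the interaction genes that passed. A gene with several probe sets is given by the brightest unless named by rank. Arc, like Chrnb4, Chrna3 and Chrna5, had no paired probe set and was not analysed here. Pts, Dlat, Xist and the other sex transcripts were named after their values were seen, as was the probe set paired with several genes. Over the average, both probe sets of Klf10 and Sox18 passed, and for Junb, Atf3 and Errfi1 the other probe set had the same sign and did not pass.

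Alternatives fixed before the data were examined were quantile normalization, median centring, 2 other filters, a floor at the 25th percentile (a signal of 11.52), eBayes without trend or robust, array weights, sex, age or title prefix as a covariate, mice of 7 weeks or older, fits of the compared groups alone, wild-type mice of the same title prefix, and each of 28 mice left out in turn. Array class was defined after the data were seen, as a Gapdh 3 prime over 5 prime log2 ratio below 0.5, and array class as a covariate, alone or with age, and fits within a class were added then, as were the seizure comparisons with wild-type mice of 1 title prefix. The fit was tested on simulated data with changed probe sets among 7350. For the average contrast it called 56% of probe sets changed by log2 0.5 and 94% of those changed by 1, and for wild-type mice 8% and 64%. Of the probe sets called there, 5.98% and 1.6% were unchanged ones. The simulated noise was independent between probe sets and held no array class, so these shares need not hold for the real arrays.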

Results

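Gene expression in the whole brain was measured in 28 mice on Affymetrix U74Av2 arrays, 1 array per mouse. The study set mice that had received no nicotine against mice killed 1 hour after a seizure brought on by injected nicotine, in 3 genotypes that differ in nicotinic acetylcholine receptors, the ion channels that nicotine opens. Untreated mice comprised 6 wild-type, 5 alpha7 +/T and 5 beta4 null animals, and seized mice comprised 3, 5 and 4 of them. The alpha7 +/T mice carry 1 altered copy of the alpha7 receptor subunit, and the beta4 null mice lack the beta4 subunit. The dose was chosen for each genotype so that the seizures were alike, which means that genotype and dose differ together in every comparison of seized mice; the amounts are not given in the sources used here. No group was injected without a seizure, so effects of nicotine, injection and handling are part of every comparison of seized with untreated mice. Whole brain pools all regions, so a change limited to 1 region is diluted.

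The arrays fell into 2 technical classes. In 9 arrays the signal of the Gapdh control set at the 3 prime end over that at the 5 prime end had a log2 ratio between -0.48 and 0.096, and in the other 19 it lay between 1.13 and 2.57. The first principal component, with 41.6% of the variance, put the 9 arrays between 36.7 and 43.7 and the 19 others between -29.5 and 6.73. The 9 low-ratio arrays belonged to alpha7 +/T mice (2 untreated, 3 seized) and beta4 null mice (2 untreated, 2 seized), and none was from a wild-type mouse. The ratio did not differ detectably between seized and untreated mice over all arrays (log2 difference -0.53, p = 0.20, two-sided permutation test). Within the classes, the Gapdh ratio was lower after seizure in the low-ratio arrays (difference -0.23, exact p = 0.016) and the beta-actin ratio was lower in the high-ratio arrays (difference -0.23, exact p = 0.034). The other control did not differ detectably in either class. Beta-actin differed by -0.075 in the low-ratio arrays (exact permutation p = 0.365) and Gapdh by -0.139 in the high-ratio arrays (exact permutation p = 0.375). These p-values are unadjusted. The second component, with 9.26% of the variance, set apart 7 untreated mice of 6 weeks with the LT title prefix, 3 wild-type and 4 alpha7 +/T, from the others. No seized mouse was 6 weeks old.

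**Figure D1:**
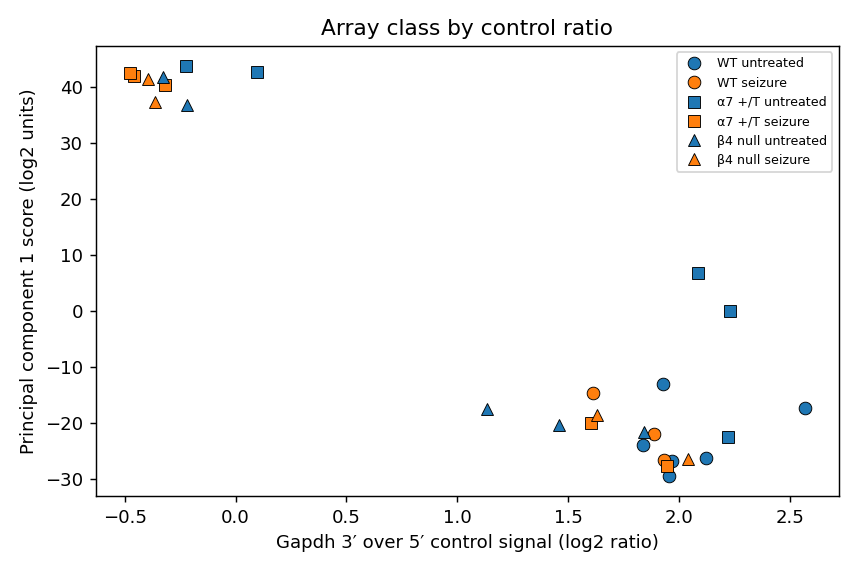
Each point is 1 array, with the log2 ratio of the Gapdh 3 prime to 5 prime control signal on the horizontal axis and the score on principal component 1 (log2 units) on the vertical axis. Shape gives genotype and colour gives treatment; the 9 low-ratio arrays lie at scores of 36.7 to 43.7 and include no wild-type mouse.

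The receptor genes were examined first. No probe set was paired with Chrnb4, Chrna3 or Chrna5, so the null label was not checked by its own transcript and these genes were not analysed here. Chrna7, which encodes the alpha7 subunit, did not pass the test in any comparison. In untreated alpha7 +/T against wild-type mice its log2 difference was 0.19 ± 0.38 (SE, limma, adjusted p = 0.73), with 4 of 5 alpha7 +/T mice above the wild-type mean, and the sign turned with array class as a covariate (-0.13). Over the 3 genotypes its seizure difference was 0.18 ± 0.24 (adjusted p = 0.90). In the beta4 null mice it was -0.056 before and 0.47 after seizure relative to wild-type mice (adjusted p = 0.95 and 0.80).

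Early-response genes were higher 1 hour after a nicotine-induced seizure. Averaged over the 3 genotypes, 24 probe sets rose and 6 fell among 7350 tested (limma, adjusted p under 0.05), which stand for 22 and 5 genes. Fos, a subunit of the AP-1 transcription factor that neuronal activity induces, rose 3.96-fold (log2 1.99 ± 0.22, SE, adjusted p = 5.19e-06), and its signal exceeded the untreated mean of the same genotype in 12 of 12 seized mice. The orphan nuclear receptor Nr4a1 rose 2.82-fold (1.49 ± 0.15, adjusted p = 1.18e-06), and Fosb rose 2.29-fold (1.197 ± 0.14, adjusted p = 1.51e-05), each in 12 of 12 mice. Atf3 rose 2.27-fold, Egr2 2.15-fold, Junb 2.11-fold, Egr1 1.52-fold and Klf10 1.51-fold. Of the 20 measured members of the list of immediate early transcription factors, 10 rose over all probe sets tested and 13 when adjusted over the list alone, with a median log2 change of 0.57 (camera, adjusted p = 8.63e-30, and adjusted p = 2.31e-05 with an estimated correlation).

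**Figure D2:**
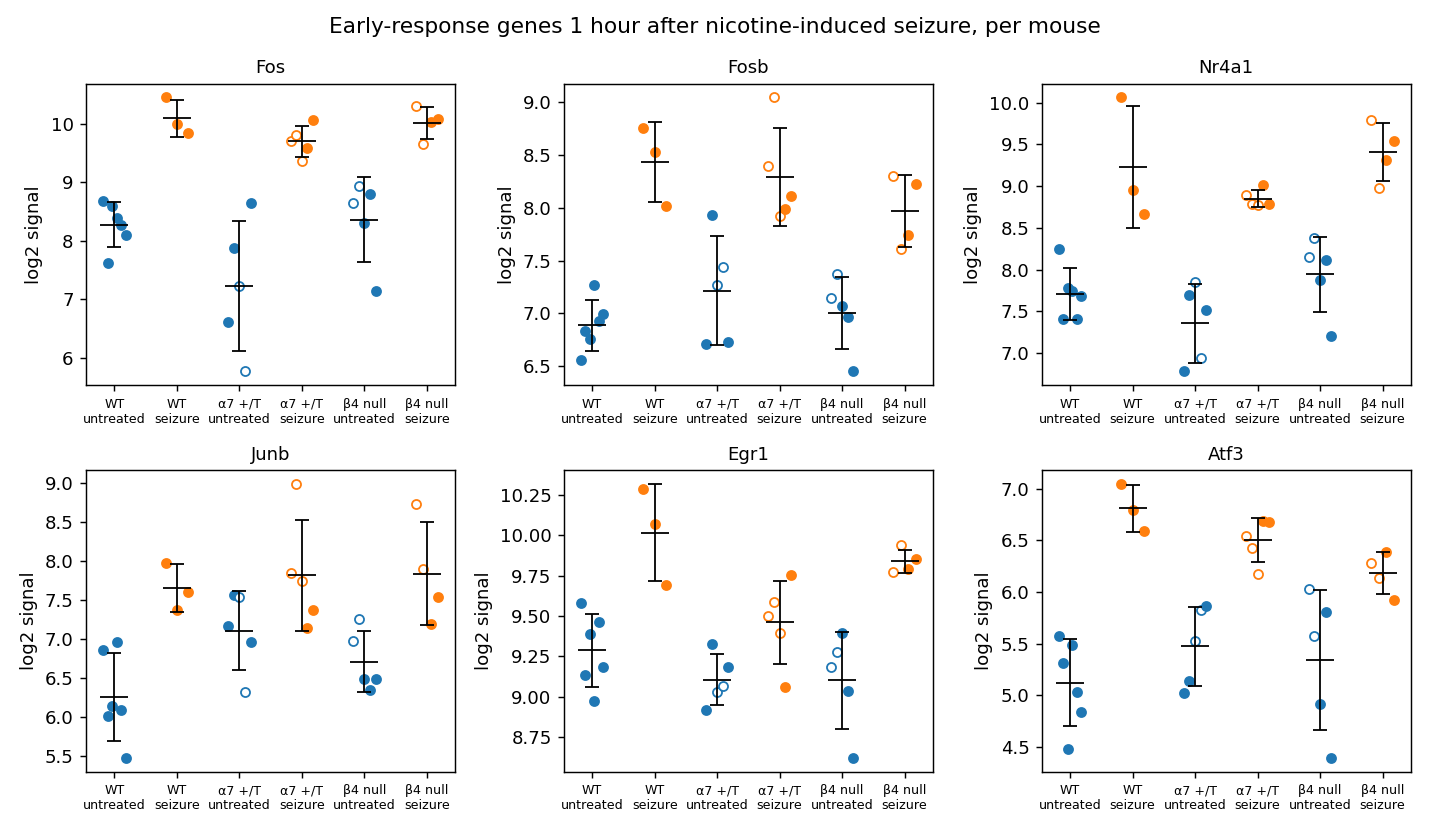
Each panel gives the log2 signal (vertical axis) of 1 gene in every mouse, by genotype and treatment (horizontal axis, untreated blue, seized orange). Bars give the mean and 1 SD and open points mark low-ratio arrays; for Fos the seized mice range from 9.36 to 10.5 and the untreated mice from 5.76 to 8.93.

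Glucocorticoid-responsive and activity-regulated effector genes were also higher as lists, with a minority of the members of each called. No hormone was measured. Among 18 measured glucocorticoid-responsive genes, 5 rose and 8 when adjusted over the list alone (median 0.27, adjusted p = 6.21e-10, and 0.0054 with an estimated correlation). They included the kinase Sgk1 (log2 1.05, 2.07-fold), Errfi1, an inhibitor of the EGF receptor (0.78, 1.71-fold), Ddit4 (0.62, 1.54-fold), which restrains mTOR, and Nfkbia (0.63), an inhibitor of NF-kB. Among 17 activity-regulated effector genes, 3 rose and 5 when adjusted over the list alone (adjusted p = 1.92e-06, and 0.0032 with an estimated correlation), namely Sgk1, Rgs2 (0.62) and Ptgs2 (1.24), the inducible prostaglandin synthase; Plk2 stood at 0.40 (adjusted p = 0.058). The call of Ptgs2 ended in 17 of 28 cases when 1 mouse was left out, and that of Rgs2 in 2. Sgk1 is on both lists, Nfkbia is also on the cytokine list, and Per1 is on the glucocorticoid and circadian lists. Of 10 MAP kinase feedback genes, 2 rose (Dusp6 0.63 and Errfi1, which is also on the glucocorticoid list) and 3 when adjusted over the list alone; the list did not pass (adjusted p = 0.068) but passed in 7 of 13 alternative settings. Dusp1 stood at 0.71 (adjusted p = 0.13) and Dusp8 at -0.41 (adjusted p = 0.51). Wdr92 also rose (0.83, 1.78-fold).

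Of 16 circadian genes, Per1 rose (0.90; not called in 8 of 28 cases with 1 mouse left out), with 2 risen when adjusted over the list alone; Bhlhe40 stood at 0.48 (adjusted p = 0.058), Clock at 0.26 and Dbp at -0.39, and the list did not pass (adjusted p = 0.24). Of 4 cytokine and NF-kB response genes, Nfkbia rose, the 1 risen gene also over the list alone, while Vcam1 (0.045), Socs1 (-0.049) and Relb (-0.0058) did not pass (list adjusted p = 0.24). Markers of neurons, astrocytes, oligodendrocytes, microglia, blood, choroid plexus, meninges, pituitary, retina, cerebellum, striatum, olfactory bulb and hypothalamus gave adjusted p between 0.24 and 0.89; over each list alone 1 neuron marker rose, and 1 oligodendrocyte and 1 hypothalamus marker fell.

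The genes that fell were Sox18, a regulator of blood vessel formation (log2 -0.54, 1.46-fold lower), Lyl1 (-0.66), Eng, an endothelial TGF-beta co-receptor (-0.57), Irf8, a factor of microglia and macrophages (-0.57), and Id3 (-0.48). Apart from Sox18 these calls were fragile: leaving out 1 mouse ended the call in 9 of 28 cases for Eng, 16 for Lyl1, 21 for Irf8 and 22 for Id3, and with median centring 2 probe sets fell in place of 6. Of 13 endothelial and pericyte markers, Eng fell, and 3 fell when adjusted over the list alone, with Vwf at -0.40 and Cldn5 at -0.53 (adjusted p = 0.20 and 0.33 over all probe sets). Rgs5 of the pericytes stood at 0.52 (adjusted p = 0.50), and the list did not pass (adjusted p = 0.55). Genes matched by a symbol pattern for transcription factor families made up 11 of the 22 risen genes (50%) and 3 of the 5 fallen genes (60%). Among the 5599 genes tested the share was 5.2% (two-sided Fisher exact test, p = 2.62e-09 and 0.00129). The pattern takes in Per1 and Btg2 and leaves out Lyl1, so these are shares of matched symbols. For the fallen genes the excess was lost at an adjusted p of 0.01 (1 of 1 gene, Fisher exact p = 0.052) and with no filter (1 of 2 genes, Fisher exact p = 0.11). The list of transcription factors as a whole had a median change of -0.015, a mean of 0.0094 and a test direction of down (adjusted p = 0.87), with 15 risen and 5 fallen when adjusted over the list alone. With array class as a covariate all 30 probe sets remained and 51 were called (40 risen, 11 fallen). In the 19 high-ratio arrays alone 12 of them were called, and in mice of 7 weeks or older 10 probe sets were called, of which 7 were shared; in neither did any gene pass as fallen. With only the wild-type mice of the B4 title prefix, 2 of them seized, 15 were called, of which 13 were among the 30, and with only those of the LT prefix, 1 of them seized, 9 were called. Array weights gave 645. With 1 mouse left out the count ran from 18 (without seized wild-type mouse 1) to 68 (without untreated alpha7 +/T mouse 5).

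The response was then examined in each genotype. In wild-type mice 4 probe sets rose and 0 fell (limma; 312 at an unadjusted p under 0.05 against 368 by chance), each in 3 of 3 seized mice: Fosb (log2 1.54 ± 0.26), Atf3 (1.69 ± 0.29), Nr4a1 (1.52 ± 0.27) and Wdr92 (1.02 ± 0.20). Fos stood at 1.82 ± 0.40 (adjusted p = 0.17), Junb at 1.39 (adjusted p = 0.45) and Egr1 at 0.73 (adjusted p = 0.22). The immediate early list rose (12 of 20 adjusted over the list alone, adjusted p = 3.04e-17, and 0.0011 with an estimated correlation), as did the effector list (1 of 17 over the list alone, adjusted p = 0.00015, and 0.020 with an estimated correlation), led by Ptgs2 at 2.12. The glucocorticoid list, with 1 of 18 risen over the list alone, passed with the preset correlation (adjusted p = 0.00015) and not with an estimated one (adjusted p = 0.13). In mice of 7 weeks or older, where 3 untreated wild-type mice remained, no probe set passed, and none did with wild-type mice of the B4 title prefix alone (2 seized, 3 untreated), while the 4 kept their sign at a median 0.978 and 0.862 of their change. Wdr92 also lost its call in 18 of 28 cases with 1 mouse left out and in 6 of 15 alternative settings. Leaving out seized wild-type mouse 1 or 2 also left 0, and leaving out untreated wild-type mouse 2 left 2.

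In alpha7 +/T mice 126 probe sets rose and 80 fell. Fos rose 5.57-fold (2.48 ± 0.36), Klf10 2.47-fold (1.30 ± 0.14), Nr4a1 2.82-fold, Sgk1 3.07-fold and Wdr92 2.15-fold, each in 5 of 5 mice. The untreated mean of Fos was low and scattered in this genotype (log2 7.22 ± 1.11, SD), against 8.27 in wild-type mice. In seized mice its mean was 9.70, against 10.1 in wild-type and 10.02 in beta4 null mice. Also higher were Ak4 (0.87), the translation factor Eif1a (1.00), the lysosomal membrane protein Lamp2 (1.19), Sdcbp (1.09), Zhx1 (0.72 in 1 probe set and -0.70, adjusted p = 0.34, in its other), Hnrnph2 (1.55) and Eloc (1.02), and lower were Sox18 (-1.12), Lyl1 (-1.22), Ginm1 (-1.47), Stk16 (-0.63), Dalrd3 (-0.77), Tmem160 (-1.32), Kansl2 (-0.54), Lamp1 (-0.77), Pigk (-1.40), Jagn1 (-0.75), Hnrnpm (-0.80) and Klf5 (-0.64). Junb stood at 0.71 and Egr1 at 0.35 (limma, adjusted p = 0.24 and 0.19), and the other probe set of Junb at 1.73. The immediate early list rose (6 of 20 over all probe sets and 11 over the list alone, adjusted p = 9.26e-10, and 0.025 with an estimated correlation). The glucocorticoid, circadian and effector lists (3, 3 and 2 risen over all probe sets, 10, 5 and 2 over the list alone) passed with the preset correlation (adjusted p = 7.14e-06, 0.014 and 0.038), and not with an estimated one (adjusted p = 0.082, 0.11 and 0.16). Their leading members were Per1 (1.44), Nr1d2 (0.80), Bhlhe40 (0.81) and Rgs2 (1.05). The 206 calls depended on the arrays used. With the compared groups alone in the fit, and so without the spread shared with the other groups, 4 were called. With array class as a covariate 978 were called, and 206 of the 206 remained. Within the high-ratio arrays 13 were called, of which 6 were among the 206, and within the low-ratio arrays 682, of which 152 were. With age as a covariate 12 were called, and the 206 kept their sign at a median 0.834 of their change. In mice of 7 weeks or older, where 1 untreated alpha7 +/T mouse remained, 8 were called, none of them among the 206, of which 188 kept their sign at a median 0.494 of their change. With only the wild-type mice of the LT prefix, which enter through the shared spread, 113 of the 206 stayed called. Centring each array on its median gave 67 risen and 67 fallen, and quantile normalization 168 and 131. With 1 mouse left out the count was 94, 77 and 670 without untreated alpha7 +/T mice 2, 3 and 5, and 119 without seized mouse 1.

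In beta4 null mice 1 probe set passed, Nr4a1 (1.47 ± 0.26, 2.76-fold, adjusted p = 0.041, 4 of 4 mice; 128 at an unadjusted p under 0.05). Fos stood at 1.65 ± 0.38 (adjusted p = 0.31), Fosb at 0.97 (0.53), Junb at 1.12 (1.00) and Egr1 at 0.73 (0.21), each above the untreated mean in 4 of 4 mice. The immediate early list rose (11 of 20 adjusted over the list alone, adjusted p = 5.99e-25, and 8.78e-05 with an estimated correlation). So did the effector, MAP kinase feedback and cytokine lists (0, 3 and 1 risen over the list alone, camera adjusted p = 0.0034, 0.0090 and 0.0076, each 0.045 with an estimated correlation). The 4 measured genes of the cytokine list were Nfkbia, Relb, Socs1 and Vcam1, none of them a cytokine or chemokine. Dusp6 stood at 0.81 and Nfkbia at 0.82, while Dusp16 and Socs1 were below 0. Over alternative settings Dusp16 ran from -0.61 to 0.00018, Socs1 from -0.74 to 0.14 and the MAP kinase list median from -0.14 to 0.17. The effector list lost its call in 3 of 14 alternative settings, the MAP kinase list in 1 of 14 and the cytokine list in 3 of 13. The glucocorticoid list, with 4 risen over the list alone, passed only with the preset correlation (adjusted p = 0.0012, and 0.15 with an estimated one). Nr4a1 was not called when any of 19 of the 28 mice was left out. It was also not called in 6 of 16 alternative settings, among them age as a covariate and either array class alone. Its log2 change ran from 1.12 to 1.705 over these 16 settings.

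Whether the response differed between genotypes was tested by the interaction. Of 7350 probe sets, 2 passed. Klf10, a zinc finger transcription factor, had seizure differences of 0.47 ± 0.15 in wild-type, 1.30 ± 0.14 in alpha7 +/T and 0.019 ± 0.14 in beta4 null mice (adjusted p = 0.018). The other, a probe set paired with several genes, had differences of 0.20, 1.41 and -0.024 (adjusted p = 0.026). For Fos, Fosb, Junb, Egr1 and Nr4a1 the interaction gave adjusted p between 0.80 and 1.00. The Junb probe sets differed in sign there (alpha7 +/T minus wild-type, -0.68 in the one given and 0.59 in the other). Neither probe set passed with age as a covariate, in mice of 7 weeks or older or within the high-ratio arrays, and with array class as a covariate 33 passed, including both. With array weights Klf10 did not pass (limma, adjusted p = 0.060). Its difference between alpha7 +/T and wild-type mice ran from 0.71 to 0.91 over 15 alternative settings. A further probe set of Klf10 had differences of 0.27, 1.25 and 0.35 and did not pass (adjusted p = 0.31). Leaving out untreated alpha7 +/T mouse 3 or 4, or seized beta4 null mouse 1 or 4, left 0, and leaving out untreated alpha7 +/T mouse 5 gave 32. Of the 30 probe sets called over the average, 29 had the same sign in all 3 genotypes, some with values near 0, and adjusted over these 30 alone the interaction passed for 5, among them Klf10, Ak4 and 1 of 2 probe sets of Sox18. The limma F test adjusted in this way gave adjusted p = 0.016 for that Sox18 probe set and 0.15 for the one given over the average. The 30 were picked by their average on the same arrays, so equal signs are partly built in. The narrowed adjustment is not independent of that choice and gives no separate support for a genotype difference.

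Untreated alpha7 +/T mice were compared with untreated wild-type mice to ask what the altered subunit changes before nicotine. By limma, 568 probe sets were higher and 609 lower. Higher were the cortical transcription factor Fezf2 (0.85), Atf4 of the stress response (0.79), Mcrip1 (0.68), Mc5r (0.80), Ap2a2 (0.82), Slc44a4 (0.79), Gtf2h4 (0.86), Vps72 (0.98), Pkig (0.79), the corticotropin-releasing hormone receptor Crhr1 (0.71), Mtfr1l (0.73) and P2rx7 (0.79). Lower were B3galt2 (-1.21), the sodium channel Scn1a (-0.92), Pag1 (-1.23), Smad1 (-0.61), Dnttip2 (-1.06), Rabggtb (-0.71), Slc31a1 (-0.93 in 1 probe set and -0.0091, adjusted p = 0.98, in its other), Xpot (-0.96), Eif1a (-0.84), Cpeb2 (-1.06), Sypl (-0.87) and Sdcbp (-0.94). Each of these 24 was on that side of the wild-type mean in 5 of 5 alpha7 +/T mice. Eif1a and Sdcbp, lower here, were among the genes higher after seizure in this genotype, and both comparisons use the same untreated alpha7 +/T arrays. These arrays also enter both tests of the glucocorticoid list, which was higher after seizure in this genotype. Glucocorticoid-responsive genes were lower as a list (4 of 18 over all probe sets and 5 over the list alone, median -0.42, adjusted p = 0.016), with Sgk1 at -1.12, Zbtb16 at -0.91, Klf9 at -0.36 and Ddit4 at -0.50; with an estimated correlation the adjusted p = 0.70. Genes of oxidative phosphorylation (3 of 64 higher and 11 lower, 4 and 12 over the list alone, adjusted p = 0.016) gave adjusted p = 0.90 with an estimated correlation, and their leading members went both ways (Ndufa10 0.48, Ndufb3 -1.24, Cox6b1 0.79, Ndufv1 1.00).

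These 1177 calls depended on which arrays were compared. With array class as a covariate 669 were called, of which 607 were among the 1177. Within the high-ratio arrays, 3 untreated alpha7 +/T against 6 wild-type mice, 3 were called, and all 1177 kept their sign. Against the 3 wild-type mice of the same title prefix, all of 6 weeks, 6 were called, and the 1177 kept their sign at a median 0.942 of their change. In mice of 7 weeks or older, where 1 alpha7 +/T mouse remained, 4 were called, and 1028 kept their sign at a median 0.38. Median centring, which moved the median of all probe sets from 0.063 to -0.18, gave 191 higher and 1256 lower, and quantile normalization 373 and 646. Without untreated alpha7 +/T mice 3, 4 and 5 the count was 60, 144 and 2041, and without untreated wild-type mice 3, 5 and 6 it was 512, 624 and 660.

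Between untreated beta4 null and wild-type mice 1 probe set passed by limma (951 at an unadjusted p under 0.05 against 368 by chance). Spg21 was 5.81-fold lower (log2 -2.54 ± 0.31, limma, adjusted p = 7.84e-05) in 5 of 5 mice, with a mean log2 signal of 6.12 ± 0.49 (SD, n = 5) against 8.66 ± 0.47 (n = 6). After seizure it was again the 1 called probe set, 7.57-fold lower (-2.92 ± 0.40, adjusted p = 0.00044) in 4 of 4 mice; array weights called 1999 probe sets in that comparison. With array class as a covariate the differences were -2.16 and -2.44. Median centring moved the median of all probe sets in untreated mice from 0.036 to -0.095 and left Spg21 as the 1 call. Spg21 was the 1 called gene and lay among the 50 measured genes on each side of Chrnb4 in gene order (1 of 100 against 0% of the others, one-sided Fisher exact test, p = 0.018), but not among the nearest 25 on each side. For alpha7 +/T mice 17 of the 100 neighbours of Chrna7 were called, against 16.7% of the others (one-sided Fisher exact test, p = 0.51).

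**Figure D3:**
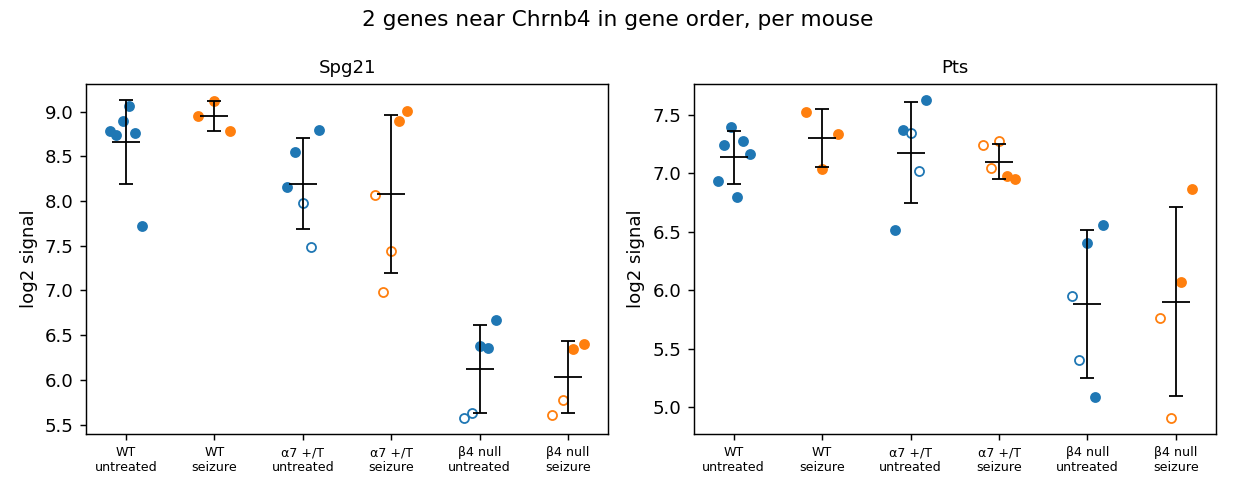
The log2 signal (vertical axis) of Spg21 and Pts, both neighbours of Chrnb4 in gene order, in every mouse by genotype and treatment (horizontal axis). Bars give the mean and 1 SD and open points mark low-ratio arrays; Spg21 lies between 5.57 and 6.67 in untreated beta4 null mice and between 7.72 and 9.06 in untreated wild-type mice.

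After seizure, alpha7 +/T and wild-type mice differed in 0 probe sets by limma (882 at an unadjusted p under 0.05 against 368 by chance; 2 without seized alpha7 +/T mouse 1), while array weights called 1007. Oxidative phosphorylation genes were lower as a list (median -0.23, adjusted p = 0.011) and synaptic vesicle genes higher (median 0.31, adjusted p = 0.040); with an estimated correlation both gave adjusted p = 0.77, and with array class as a covariate 0.92 and 0.87. The leading members were Ndufab1 (-0.73), Ndufb9 (-0.45), Cox5b (-0.51), Ndufa8 (-0.59), Syt11 (2.18), Cplx1 (1.42), Nsf (0.95) and Syt1 (1.496), none of which passed. Median centring moved the median of all probe sets from 0.013 to -0.20 and left 0 calls. In beta4 null against wild-type mice after seizure, synaptic vesicle and neuron marker lists were higher (both adjusted p = 0.043; with an estimated correlation adjusted p = 0.79, and 0.60 with array class as a covariate), with Syt11 at 1.87 and Uchl1 at 0.68, while Gad1 stood at -0.24. No member of these lists passed over the list alone. The count of probe sets called was 3 without seized beta4 null mouse 4.

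Sex was compared with group in the model. By limma 4 probe sets passed, with Eif2s3y lower (log2 -4.03) and Eif2s3x higher (0.55) in mice labelled female. Xist stood at 2.69 (adjusted p = 0.063). The seizure by sex interaction called 0 probe sets (589 at an unadjusted p under 0.05; smallest adjusted p = 0.23). In untreated wild-type mouse 5 and untreated beta4 null mouse 3 the signals of Eif2s3y and Uty did not match the sex label. Both mice entered these tests as labelled, which limits them, and no fit with other labels was run.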

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

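The tests of array class, of the 6-week mice and of the neighbours at an unadjusted p were chosen only after the results were seen; the splits of the samples and the neighbour test at the adjusted threshold were planned.

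Single mice stood apart in 4 of 115 groups tested over 23 measures, about as chance gives at 1 in 20. Wdr92 was lowest in untreated beta4 null mouse 1 (log2 signal 9.44, others 9.87 to 10.0). Sox18 was highest in seized beta4 null mouse 2 (6.30, others 6.02 to 6.05). Irf8 was lowest in seized alpha7 +/T mouse 1 (4.54, others 5.01 to 5.19). Spg21 was lowest in untreated wild-type mouse 6 (7.72, others 8.74 to 9.06). The seizure response differed between genotypes for Klf10 (alpha7 +/T minus wild-type, log2 0.83) and for a probe set paired with several genes (1.22). In 5 of 100 shuffles of genotype within treatment as many interaction calls were made (real 2, highest other 9), so chance is not excluded for that count.

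Between untreated alpha7 +/T and wild-type mice 1177 probe sets differed. No other of 100 splits of these mice reached this (1 of 100, highest other 794), which argues against chance alone. The highest other split put the 2 low-ratio arrays on one side, as the real grouping does. Array class moved the same probe sets in the same direction: measured within beta4 null mice alone, its effect had the sign of the difference for 87% of them, with a signed median of 0.356 (highest of the other relabellings 0.238), which falls short of the 1.76 needed to be the whole cause, and with the class as a covariate 607 stayed called and the 1177 kept a median 0.758 of their change. The 6-week LT mice as a batch or age gave a signed median of 0.082 among wild-type mice (needed 2.34, highest other 0.121). This argues against a batch or age shared with the wild-type mice as the whole cause. Against the 3 wild-type LT mice, all of 6 weeks, a median 0.942 of the change was kept and 6 were called. The 1177 were picked with these same arrays, so that share is partly built in and decides little. In mice of 7 weeks or older, with 1 alpha7 +/T mouse, a median 0.38 was kept, so a part is not excluded. That mouse, untreated alpha7 +/T mouse 5, was 8 weeks old. On component 2 it scored 0.12, against -37.91 to -18.21 in the 4 mice of 6 weeks. Without it the count rose to 2041. Class may therefore account for part; genotype, and a batch within the alpha7 +/T mice, stay open.

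Seizure in alpha7 +/T mice called 206 probe sets, and 6 of 100 splits called as many, so chance is not excluded. The highest split, 1795, parted the 5 low-ratio from the 5 high-ratio arrays, which points to structure among the arrays; the count was 978 with class as a covariate, 13 within high-ratio and 682 within low-ratio arrays. With class as a covariate 100% of the 206 stayed called, which says little, since the class differs little between untreated and seized mice of this genotype. Within the high-ratio arrays 6 of the 206 stayed called and within the low-ratio arrays 152. All 206 kept their sign there, at a median 0.856 and 1.2 of their change. This argues against array class as the whole cause, although the 206 were picked from these same arrays. A batch or age of the 6-week LT untreated mice had the matching sign for 74.3% of them among wild-type mice, with a signed median of 0.158 (highest other 0.14), against 0.971 needed for the whole; the 206 kept a median 0.834 of their change with age as a covariate and 0.494 in mice of 7 weeks or older, with 1 untreated alpha7 +/T mouse. It may add to the count, and a batch within this genotype stays open, because 4 of 5 untreated alpha7 +/T mice were 6 weeks old and no seized mouse was.

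Spg21 was lower in beta4 null mice, and 3 of 100 splits called as many probe sets (real 1, highest other 2), so such a count was rare by regrouping. The splits count any probe set and do not test Spg21 itself, whose own limma test gave adjusted p = 7.84e-05. Array class is argued against, since the difference was -2.156 with it as a covariate. A candidate explanation is DNA of another strain kept around the altered locus: the neighbour test gave p = 0.0179, resting on Spg21 alone, and at an unadjusted p under 0.01, 10 of 100 neighbours against 2.71% of other genes differed (one-sided Fisher p = 0.000494), among them Pts (log2 -1.25, adjusted p = 0.27) and Dlat (-0.56, adjusted p = 0.32). An effect of losing the subunit on these genes was not tested and stays open, and neighbouring genes are not independent.

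For the other comparisons, the average over genotypes had 30 calls and no other of 100 splits reached it (1 of 100, highest other 1). This argues against chance alone. The splits do not test age, and no seized mouse was 6 weeks old. For wild-type mice 2 of 84 splits had as many as 4 (highest other 9), so such a count was rare by regrouping. Chance is not excluded, since the highest regrouping of the same mice called 9. For beta4 null mice 7 of 100 splits had as many as 1, so chance is not excluded for that count. The highest, 2186, put the 4 low-ratio arrays on one side and so points to structure among the arrays. The count was 4 with class as a covariate, 0 within high-ratio and 5 within low-ratio arrays. After seizure, beta4 null against wild-type had 1 call, reached by 2 of 35 splits (highest other 2), so these splits alone do not exclude chance for the count; the call was Spg21, also called between untreated mice. A count of 0 is reached by every split, so the splits decide nothing for alpha7 +/T against wild-type after seizure (0 calls, 56 of 56) or for seizure by sex (0 calls, 100 of 100, highest other 1). In the former the highest other, 1395, had the 3 low-ratio arrays on one side, again structure, and with class as a covariate the count was 0.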

How the results depend on the processing

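Settings with array class, the seizure comparisons with wild-type mice of 1 title prefix and the Chrna7 neighbours at an unadjusted p were chosen after the data were seen; the others were planned. Where a value moved, the cause was not tested, except that fewer mice leave less power. The 30 calls of the average contrast held within 1.5 times in 11 of 18 settings. They became 645 with array weights, 19 with age, 10 in mice of 7 weeks or older, 51 with array class, 12 in high-ratio arrays, 9 with only LT (1 seized) and 15 with only B4 (2 seized) wild-type mice, and 18 to 68 with 1 mouse left out (18 without seized wild-type mouse 1, 68 without untreated alpha7 +/T mouse 5). The lists called in this contrast went from 3 to 7 in mice of 7 weeks or older.

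Wild-type seizure calls (4) became 35 with array weights, 0 in mice of 7 weeks or older, 9 in high-ratio arrays and 0 with only LT (1 seized, too few to weigh) or only B4 wild-type mice, and 0 to 5 with 1 mouse left out (2 without untreated wild-type mouse 2, 0 without seized mouse 1 or 2). The alpha7 +/T seizure calls (206) became 1.3e+02 with median centring (67 risen and 67 fallen), 12 with age, 8 in mice of 7 weeks or older, 978 with array class, 13 in high-ratio and 682 in low-ratio arrays, 84 with class and age, 1.2e+02 with only LT wild-type mice (113 of the 206 kept) and 4 with the compared groups alone; with 1 mouse left out they ran from 77 to 670 (94, 77 and 670 without untreated mice 2, 3 and 5, 119 without seized mouse 1). The beta4 null seizure call (1) became 2 with median centring, 21 with array weights, 4 with class, 4 with class and age, 5 in low-ratio arrays, and 0 with no filter, no variance trend, age, mice of 7 weeks or older, high-ratio arrays or the compared groups alone, and 0 to 1 with 1 mouse left out.

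Untreated alpha7 +/T calls (1177) became 561 with age, 102 with title prefix, 4 in mice of 7 weeks or older, 669 with class, 3 in high-ratio arrays, 448 with class and age, 538 with the compared groups alone and 6 with wild-type mice of the same prefix; with 1 mouse left out they ran from 60 to 2041 (512, 624 and 660 without wild-type mice 3, 5 and 6; 60, 144 and 2041 without alpha7 +/T mice 3, 4 and 5). The untreated beta4 null call became 0 in mice of 7 weeks or older. After seizure, array weights gave 1007 calls for alpha7 +/T (0 in the other settings; 0 to 2 with 1 mouse left out, 2 without seized alpha7 +/T mouse 1) and 1999 for beta4 null (1 in the other settings; 1 to 3, 3 without seized beta4 null mouse 4). Interaction calls (2) became 1 with median centring, 1 with no variance trend, 0 with age, 33 with class, 0 in high-ratio arrays, 4 with class and age and 0 with only LT wild-type mice (1 seized, too few to weigh), and 0 to 32 with 1 mouse left out (0 without untreated alpha7 +/T mouse 3 or 4 or seized beta4 null mouse 1 or 4, 32 without untreated alpha7 +/T mouse 5, 1 in 8 further cases).

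Chrna7 never passed. Its untreated alpha7 +/T difference turned to -0.046 with median centring, -0.071 with array weights, -0.13 with class, -0.26 in high-ratio arrays and -0.15 with class and age, and ran from -0.047 to 0.67 with 1 mouse left out. Its sign also turned in wild-type seizure (0.062 with sex; -0.22 to 0.077 with 1 mouse left out), in alpha7 +/T seizure (-0.026 with class, -0.22 in low-ratio arrays; -0.34 to 0.46), after seizure in alpha7 +/T against wild-type (-0.094 with class, -0.10 in high-ratio arrays, -0.060 with class and age), in untreated beta4 null mice (-0.20 to 0.11) and in the interaction (-0.28 to 0.52). None of the following passed where its sign turned. In mice of 7 weeks or older Vps72 was -0.041 for untreated alpha7 +/T, the interaction of Fos was -0.78 and of Fosb 0.19, and Dbp was 0.022. The interaction of Nr4a1 was 0.062 with quantile normalization, 0.083 with array weights, 0.0088 with age and 0.046 in high-ratio arrays, and -0.31 to 0.39 with 1 mouse left out. Over the average, Vcam1 was -0.066 in high-ratio arrays (-0.0062 to 0.077), Socs1 0.012 with class and 0.0071 with class and age (-0.22 to 0.16), and Relb 0.080 with array weights (-0.12 to 0.11). In beta4 null seizure Dusp16 was 0.00018 with array weights, Relb -0.030 and Socs1 0.14 in low-ratio arrays, and Vcam1 -0.055 in high-ratio arrays (-0.042 to 0.10). After seizure in beta4 null mice the neuron marker list had a median of 0.068 with the direction of its test turned and Syt1 was -0.079, both in high-ratio arrays. The transcription factor list turned in its test, with medians of 0.0015 with the mean filter, -0.022 in mice of 7 weeks or older and 0.0043 in high-ratio arrays (-0.029 to -0.0020 with 1 mouse left out).

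Besides the beta4 null effector, MAP kinase and cytokine lists after seizure, lists that lost their call in some settings, the estimated correlation included, were glucocorticoid (1 of 13 settings in wild-type, 1 of 14 in alpha7 +/T and 3 of 14 in beta4 null seizure; 2 of 13 in untreated alpha7 +/T), effector (5 of 14 in alpha7 +/T seizure), circadian (4 of 14 there), oxidative phosphorylation (6 of 13 before and 6 of 13 after seizure in alpha7 +/T against wild-type), synaptic vesicle (6 of 13 in alpha7 +/T and 7 of 13 in beta4 null against wild-type after seizure) and neuron markers (6 of 13 in the latter, besides 1 turned).

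The share of genes matched by the transcription factor pattern among fallen genes was 100% at an adjusted p of 0.01 (1 gene, Fisher exact p = 0.052) and 50% with no filter (Fisher exact p = 0.11). Called neighbours of Chrnb4 were 0 of 50 with 25 on each side. Those of Chrna7 turned below the share elsewhere, at 7 with 25 and 30 with 100 on each side, 0 with prefix-matched mice and 9 with class. At an unadjusted p under 0.01, 18 of 100 neighbours of Chrna7 differed against 18.6% of other genes (one-sided Fisher exact p = 0.60), and 14 against 7.84% with prefix-matched mice (one-sided Fisher exact p = 0.026). The sex comparison called 7 with no filter and 15 with class. No seizure by sex call appeared in any setting. No paired analysis was possible because the labels give each mouse its own animal number and no replicate number, and the numbers used here only name mice in sample order.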

Other observations

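The sex labels were set against sex chromosome transcripts as a check, after the data were seen. Untreated wild-type mouse 5 is labelled female, and its signals were 1.44 for Xist, 89.1 for Eif2s3y and 27.1 for Uty. Untreated beta4 null mouse 3 is labelled male, and its signals were 9.95, 7.46 and 2.17. Both mice enter the comparison of the sexes as labelled. An exchange of these 2 mice between genotypes is argued against by Spg21, whose log2 signal was 8.76 in the former and 6.38 in the latter, each within the range of the other untreated mice of its labelled genotype. Their treatment labels were not checked by these transcripts. In the untreated alpha7 +/T mice Xist did not part the sexes (20.9 in female mouse 4 and 22.9 in male mouse 5). Eif2s3y was higher in the males of that group than in the females. Its lowest male value was 27.3 in mouse 3, whose Uty signal was 4.43, against 10.8 and 3.14 in female mouse 1.

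Several lists named in the methods gave no call over the average contrast and are recorded as values. Heat shock proteins and chaperones had 0 of 19 members changed (adjusted p = 0.87), hypoxia and glycolysis genes 0 of 19 (0.40), GABA genes 0 of 11 (0.24; 1 risen over the list alone), glutamate receptors 0 of 9 (0.74), voltage-gated channels 0 of 17 (0.96), neuropeptides 0 of 19 (0.74), monoamine genes 0 of 9 (0.87), cholinergic genes 0 of 5 (0.90), synaptic vesicle genes 0 of 16 (0.24), oxidative phosphorylation genes 0 of 64 (0.74) and ribosomal proteins 0 of 26 (0.26). Median and mean change differed in sign for voltage-gated channels (0.056 and -0.0047), neuropeptides (0.047 and -0.035), cholinergic genes (-0.064 and 0.049) and hypothalamus markers (0.034 and -0.066), and for oligodendrocyte markers both were above 0 (0.022 and 0.0018) with a test direction of down.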
